A study of Homo sapiens with 12 samples.

How the data were processed

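The series holds 12 RNA sequencing libraries from Caco2, an established human colon epithelial cell line, in 3 groups of 4 libraries. PLEKHA7 immunoprecipitates were made from formaldehyde-crosslinked cells with an antibody to the junction protein PLEKHA7, IgG immunoprecipitates were made in parallel from the same lysates, and total RNA came from the same cells. Each of the 4 experiments gave 1 library per group. Per the labels' protocols, cells were grown to confluency and libraries were made with a stranded total RNA kit and sequenced as read pairs. The submitters' processing notes name the hg19 genome build, CASAVA 1.8.4, TopHat2 2.0.12, TopHat, Bowtie and Picard 1.140 without saying what each did. The program that counted reads per exon is not given in the sources used here.

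The deposited table lists exons, and per the file headers its values are counts per exon and RPKM per exon for each library. The deposited counts were whole numbers without normalization. The deposited RPKM values equalled the count divided by exon length and by 1 read total per library, and these totals were recovered from the values. The table had 1195408 lines over 562235 distinct intervals, because an exon was repeated for each transcript that held it, and every interval carried the same counts at each repeat. Gene counts were the sum of the distinct exon intervals (chromosome, start and end) of a gene symbol, each interval used once per gene, which gave 55773 symbols. Intervals of a gene can overlap and a read pair can fall in several, so gene counts are not numbers of molecules, and intervals and floors derived from them cover counting error only. The 122 symbols found on more than 1 chromosome were kept as single genes. No column was left without a sample. The strand of a gene was inferred from the order of its exons in the deposited table. It matched the reference annotation, GENCODE version 29, for 98.62% of 18766 genes compared by symbol. First and last exons were the outermost intervals in that direction. Coding bases of PLEKHA7 exons came from GENCODE version 29 through exon identifiers. Positions are those of the deposited table on hg19.

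Gene counts per library were 501091 to 1950500 for IgG, 31254397 to 64908672 for PLEKHA7 and 58245803 to 125931297 for total RNA. A count of 0 in a single library allows up to 3 counts, which is 1.54 to 5.99 CPM (counts scaled to 1e6 per library) in IgG libraries, 0.046 to 0.096 in PLEKHA7 libraries and 0.024 to 0.052 in total RNA libraries. Over the 4 IgG libraries together 3 counts are 0.696 CPM when library sizes are those of the tested genes scaled by TMM, as for the means, and this group limit was used wherever all IgG libraries had 0 counts.

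Each pair of groups was fitted alone with edgeR 4.0.16 (quasi-likelihood F test, robust), TMM normalization and filterByExpr with its default minimum of 10 counts, in R 4.3.3. P values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Groups were the only term. Because experiments share lysates and cells, every comparison was also fitted with the experiment as a block, and blocked counts are printed beside the unblocked ones. For lists, and for genes named outside the lists, the text says where the block made or ended a call. In blocked fits with IgG, p values of many genes were close to normal-distribution values for the fold change over its standard error. They lean on a spread shared across genes more than on the few libraries, so calls made by the block alone are uncertain. Residual correlations between same-numbered libraries were weak, from −0.195 to 0.258. Between differently numbered libraries they ran from −0.34 to 0.444, so they give no evidence for the numbering as a pairing. Log2 fold changes and standard errors (SE) come from these fits, and means with standard deviations (SD) are over the 4 libraries of a group in TMM-normalized CPM. The number of experiments showing a direction compares same-numbered libraries.

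Genes enriched over both controls were those called higher against IgG and against total RNA. Since both comparisons share the PLEKHA7 libraries, the overlap was set beside 10 simulations of unchanged libraries. These called almost no gene, so lists as long as the real ones were taken from them by smallest p; this form was chosen after the overlap was seen. The correlation across genes of both immunoprecipitates over total RNA shares the total RNA libraries, so 20 simulations of unchanged libraries and a split of the total RNA libraries into separate pairs were run.

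The 20 gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and, as an alternative, an estimated correlation, adjusted over the lists of a comparison. The lists are adherens junction, tight junction and desmosome, growth and transformation, immediate early, microRNA and RISC, cytosolic ribosome, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, histone, zinc finger, small non-coding, nuclear long non-coding, enterocyte, cell cycle, Wnt target, endoplasmic reticulum stress and secretory, actin and microtubule, goblet and endocrine, fibroblast, and immune genes. The comparisons, tests, lists and the rule for named genes were fixed before the data were examined. That rule names PLEKHA7, CDH1, CTNND1, MYC, JUN, CCND1, SNAI1, ACTB and GAPDH throughout. In comparisons with PLEKHA7 it adds the 10 largest rises and 10 largest falls among called genes with a group mean of at least 5 CPM and the same direction in all 4 experiments. In the comparison of IgG with total RNA it adds 5 of each, and where fewer than 10 genes passed it adds the 10 with the smallest p. Up to 4 members per list with the smallest adjusted p are also named. Other genes named in the text were chosen after their values were seen.

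Shares of counts by RNA class and the ratio of counts in the last to the first exon (genes with at least 4 exons and at least 10 counts over both exons in every library compared, 0.5 added to each count) were compared with exact two-sided permutation tests. With 4 libraries against 4 the smallest p these can give is 0.0286.

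Alternatives fixed before the data were examined were size factors of the DESeq2 kind, library totals, the DESeq2 1.42.0 Wald test, no low-count filter, and at least 50 counts in at least 4 libraries. Also fixed then were the experiment block, all 12 libraries in 1 fit, all exon lines summed, non-overlapping exon intervals, removal of mitochondrial and small non-coding genes, an added 2-fold threshold and leaving out each library. Alternatives chosen after seeing the data were the read totals behind the deposited RPKM values, with and without the block, experiments 1 and 4 or 2 and 3 alone, because the total RNA libraries fell into these pairs, and removal of a smooth trend on exonic length and GC content (mgcv 1.9.3), with and without the block.

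The pipeline was tested on simulated data built from these libraries with changes of known size. Against IgG, edgeR recovered 0% of 2-fold, 2.2% of 4-fold, 6.8% of 8-fold and 54.8% of 64-fold changes. For PLEKHA7 against total RNA it recovered 18.8%, 55.3%, 82.2% and 95.2%, and for IgG against total RNA 0%, 0%, 0% and 37%. False calls numbered 1, 5 and 0 over the genes tested. The 64-fold changes were added to this test after the smaller ones had shown little recovery. Other software was Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Raw reads were not analysed here.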

Results

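RNA was sequenced from 3 sources in Caco2 cells, a human colon epithelial line that forms polarised sheets. The PLEKHA7 immunoprecipitates were made from crosslinked cells with an antibody to PLEKHA7, a protein of the zonula adherens, the belt of adhesion between epithelial cells. IgG immunoprecipitates from the same lysates measured unspecific RNA, and total RNA from the same cells measured what the cells contained. There were 4 libraries per group, 1 from each of 4 experiments. The design asks which mRNAs are enriched at the zonula adherens over both controls. Gene counts in experiments 1 to 4 were 1950500, 501091, 1550381 and 634041 for IgG. They were 55600909, 64908672, 54170941 and 31254397 for PLEKHA7, and 125931297, 70085525, 58245803 and 96958123 for total RNA. Between 5535 and 10694 genes had at least 10 counts in an IgG library, 19411 to 21302 in a PLEKHA7 library and 20616 to 23878 in a total RNA library. Gene counts per read behind the deposited RPKM values were 0.061 to 0.193 in IgG libraries, against 1.05 to 1.63 in PLEKHA7 and 0.983 to 1.92 in total RNA libraries. Spearman correlations between libraries of a group, across genes that are not independent replicates, were 0.538 to 0.647 for IgG, 0.942 to 0.968 for PLEKHA7 and 0.981 to 0.988 for total RNA. On the principal component plane, whose axes held 46.7% and 17% of the variance, the IgG libraries lay apart from one another and from the other 8 libraries.

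**Figure D1:**
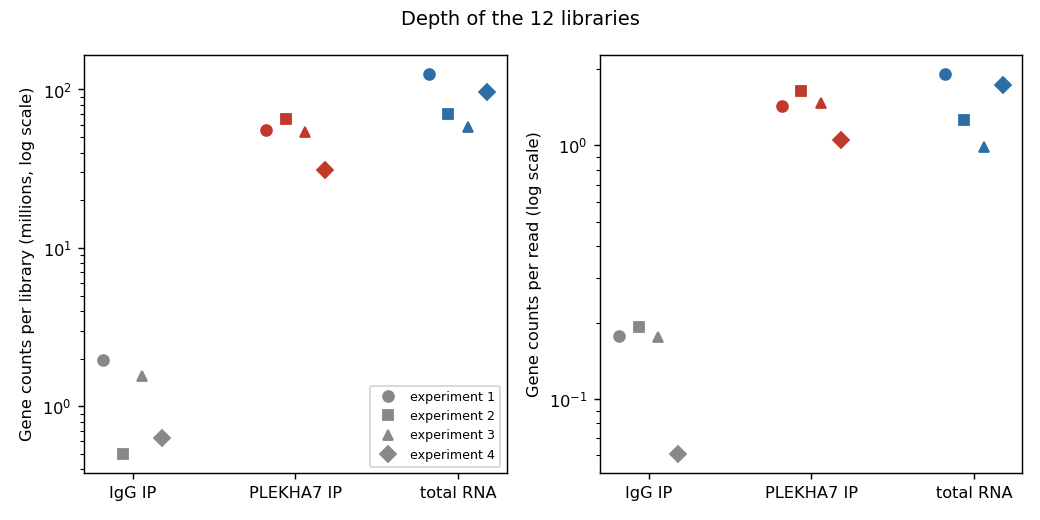
Gene counts of each library (left) and gene counts per read behind the deposited RPKM values (right), on log axes, for the 3 groups, with 1 point per experiment. The IgG libraries lie between 501091 and 1950500 gene counts and 0.061 and 0.193 counts per read, below all PLEKHA7 and total RNA libraries.

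The comparison of PLEKHA7 with total RNA asks which transcripts the immunoprecipitates held beyond their level in the cells. The PLEKHA7 transcript itself showed the largest rise by the rule for named genes, with a log2 fold change of 4.98 (SE 0.23, edgeR adjusted p = 1.43e-06) and 939 ± 171 CPM against 29.8 ± 7.37 CPM (SD, n = 4). JUN, a transcription factor of the AP-1 family, rose by 3.33 (SE 0.29), and MYC, a transcription factor that drives growth, rose by 1.78 (SE 0.20). CCND1, the cell cycle regulator cyclin D1, rose by 0.92 (SE 0.16). CDH1, which encodes the adhesion receptor E-cadherin, fell by 1.20 (SE 0.15, edgeR adjusted p = 0.000114), and its level was lower in 4 of 4 experiments. CTNND1, which encodes the E-cadherin partner delta catenin, had a log2 fold change of 0.23 and an edgeR adjusted p of 0.221.

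Of 20801 genes tested with edgeR, 8431 changed, 4106 higher and 4325 lower in the PLEKHA7 immunoprecipitates. With the experiment as a block the count was 8142, 3746 higher and 4396 lower. A change of at least 2-fold was seen for 2701 of the higher and 2645 of the lower genes. After PLEKHA7, the largest rises were those of the transporter gene SLC35D3 (log2 fold change 4.07, though its mean was 16.8 CPM here and 975 ± 933 CPM in IgG), SNRNP70 (3.80), RP11-553L6.5 (3.79), FAM72A (3.62), the nuclear receptor NR2F1 (3.55), the repressor ZBTB7A (3.40), JUN, RP1-261G23.7 (3.33) and the AP-1 gene FOSB (3.32). SNRNP70, which encodes a protein of the spliceosomal U1 particle, stood at 3439, 2177 and 2157 CPM in experiments 1 to 3 and at 161 CPM in experiment 4, against 143 ± 10.1 CPM in total RNA. It did not pass with the block (log2 fold change 3.35, edgeR adjusted p = 0.0729). FAM72A has near-identical paralogs, which can share reads. The largest falls were in small non-coding RNAs and pseudogenes, many with close copies elsewhere in the genome. The RNA of the signal recognition particle and its relatives fell, with RN7SL4P at −10.40, RN7SL3 at −8.90, RN7SL2 at −6.78, RN7SL128P at −6.38 and RN7SL1 at −6.30. The symbol 7SK, which sums copies on 7 chromosomes, was at −8.29 and RN7SK, the 7SK gene on chromosome 6, at −4.75. Other falls were RPL39P3 at −6.21, AC084082.3 at −5.75 (−11.74 to −5.25 without single libraries), SNORA71D at −5.24 and the vault RNA VTRNA1-3 at −5.23. ACTB fell by 0.94 and GAPDH by 1.60, and SNAI1 had a log2 fold change of 1.10 (edgeR adjusted p = 0.139). The 4 total RNA libraries fell into the pairs 1 with 4 and 2 with 3. Tested alone, experiments 1 and 4 gave 722 genes (182 higher, 540 lower) and experiments 2 and 3 gave 7563. With all 12 libraries in 1 fit the count was 230 (65 higher, 165 lower). With the read totals behind the deposited RPKM values as library sizes it was 5422 genes (3807 higher, 1615 lower) with the median of all genes at 0.288. ACTB then no longer passed (−0.65, edgeR adjusted p = 0.184). With library totals alone 70.6% of 9041 genes were higher, with a median of 0.379.

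**Figure D2:**
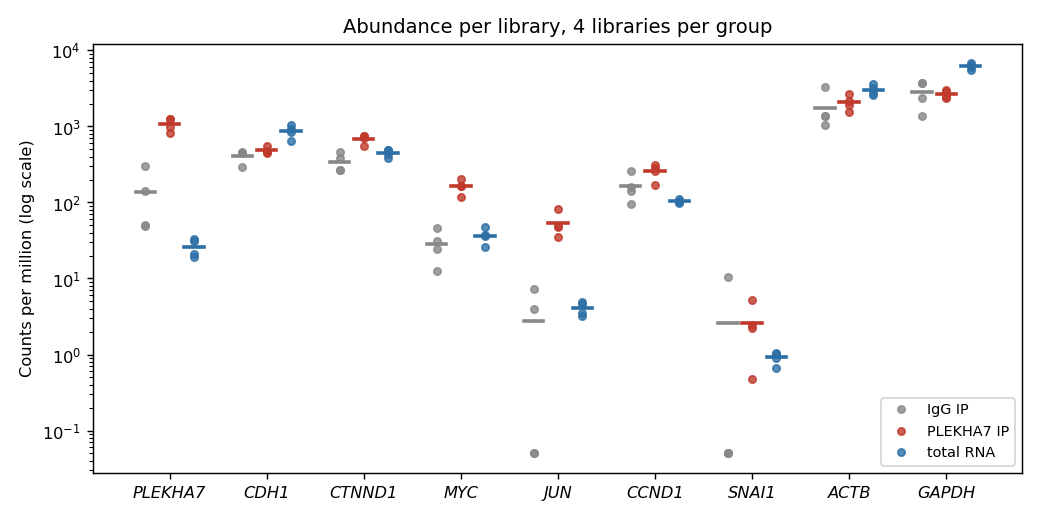
CPM of the library's gene counts, without a TMM factor and on a log axis, of the 9 genes named throughout, with 1 point per library and the group mean as a line. PLEKHA7 lies between 812 and 1248 CPM in its own immunoprecipitates, between 48.7 and 303 CPM in IgG and between 19.2 and 33.2 CPM in total RNA; counts of 0 (2 IgG libraries for JUN and 3 for SNAI1) are drawn at 0.05 CPM.

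Of the gene lists, 5 were higher in the PLEKHA7 immunoprecipitates than in total RNA. Among immediate early genes, which respond quickly to stimuli, 21 of 27 rose and none fell, with IER3 at a log2 fold change of 3.17, CYR61 at 2.65 and FOSL2 at 2.07 (camera adjusted p = 6.05e-11; adjusted p = 0.0812 with an estimated correlation). Of 447 zinc finger genes, many of them transcriptional repressors, 326 rose and 2 fell, among them ZNF778 (2.69), ZNF134 (2.63), ZNF608 (2.41) and ZNF367 (2.24). Adjusted over the list alone, 340 rose and 5 fell (camera adjusted p = 2.2e-31; adjusted p = 0.0352 with an estimated correlation). Of 20 Wnt target genes 12 rose and none fell, including RNF43 (2.96), ZNRF3 (2.20) and AXIN2 (2.10), feedback inhibitors of the pathway (camera adjusted p = 7.57e-06; adjusted p = 0.224 with an estimated correlation). In the growth and transformation list 20 of 33 rose and 2 fell, including SOX2 (1.97), SOX4 (1.70) and the cell cycle inhibitor CDKN1B (1.48). Its camera adjusted p was 1.59e-07, with adjusted p = 0.0352 with an estimated correlation. In the microRNA and RISC list 11 of 25 rose and 3 fell, with the silencing factors TNRC6C at 2.56, TNRC6A at 2.28, TNRC6B at 1.71 and AGO2 at 1.33 (camera adjusted p = 0.00127; adjusted p = 0.0441 with an estimated correlation). After a trend on length and GC content was removed, 7 of the 25 were higher and 4 lower, with the median going from 0.52 to 0.11. For these 4 lists other than the zinc fingers, the counts adjusted over the list alone were the same as over all genes.

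Lists of the translation and energy machinery were lower. Of 84 cytosolic ribosomal protein genes 74 fell and none rose, or 75 adjusted over the list alone, with RPL36A at −2.38 (camera adjusted p = 2.12e-38; adjusted p = 0.0606 with an estimated correlation). Of 74 nuclear genes of oxidative phosphorylation 73 fell, both over all genes and adjusted over the list alone, with NDUFC2 at −2.40 and COX6B1 at −2.18 (camera adjusted p = 1.29e-45; adjusted p = 0.0441 with an estimated correlation). All 13 mitochondrially encoded mRNAs fell, both over all genes and adjusted over the list alone, with MT-CO3 at −4.42 and MT-CYB at −3.75 (camera adjusted p = 2.85e-29; adjusted p = 0.0352 with an estimated correlation). Of 66 histone genes 56 fell and 1 rose, or 58 and 1 adjusted over the list alone, with HIST1H4C at −2.57 (camera adjusted p = 9.36e-30; adjusted p = 0.0441 with an estimated correlation). Of 242 small non-coding genes 84 fell and 11 rose, or 81 and 10 adjusted over the list alone. After the length and GC trend was removed, 42 of the 230 with a GC value were lower and 35 higher, with the median going from −1.42 to −0.28. RPPH1, the RNA of ribonuclease P, fell by 4.01 and SNORA79 by 3.32, whereas SNORD108 rose by 3.69 (camera adjusted p = 1.18e-06; adjusted p = 0.224 with an estimated correlation). SNORD108 lies within SNHG14, which rose by 1.98, and the sources do not say whether counting used the strand.

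The junction lists moved in both directions. In the adherens junction list 9 of 29 genes rose, PLEKHA7 itself among them, and 6 fell, over all genes and adjusted over the list alone. Cingulin (CGN) was at 1.90, beta-catenin (CTNNB1) at −1.53 and P-cadherin (CDH3) at −1.08, and the list as a whole did not pass (camera adjusted p = 0.152). In the tight junction and desmosome list 9 of 29 rose and 5 fell, over all genes and adjusted over the list alone, including periplakin (PPL, 1.86), desmoplakin (DSP, 1.76), PARD6B (0.94) and the adhesion molecule F11R (−1.18). That list did not pass either (camera adjusted p = 0.417), and its median of −0.01 and mean of 0.11 differ in sign. After the length and GC trend was removed, 6 of 25 adherens junction genes were higher and 10 lower, and 4 of 28 tight junction and desmosome genes were higher and 6 lower. Enterocyte genes fell, 13 of 22 with 1 higher over all genes and adjusted over the list alone. The lipoprotein gene APOA1 was at −2.42 and the adhesion gene CDH17 at −1.61, while the intestinal transcription factor CDX2 rose by 1.70 (camera adjusted p = 0.000374; adjusted p = 0.0352 with an estimated correlation). In the endoplasmic reticulum stress and secretory list 17 of 30 fell and 2 rose, the same counts as adjusted over the list alone, with the chaperones PDIA6 at −1.99 and CALR at −1.82 (camera adjusted p = 3.85e-06; adjusted p = 0.0441 with an estimated correlation). In the actin and microtubule list 17 of 34 fell and 4 rose, or 18 and 4 adjusted over the list alone, with the myosin light chain MYL6 at −1.84 (camera adjusted p = 0.0052; adjusted p = 0.324 with an estimated correlation). In the cell cycle list 17 of 30 fell and 3 rose, or 17 and 6 adjusted over the list alone, with TYMS at −1.74 (camera adjusted p = 0.00462; adjusted p = 0.324 with an estimated correlation). The cell cycle and actin lists did not pass with the deposited read totals (camera adjusted p = 0.12 and 0.0907). Of 12 nuclear long non-coding RNAs, SNHG14 (1.98), LINC00657 (1.66) and TUG1 (0.93) rose and JPX (−0.97) fell, both ways of adjusting giving 3 and 1, and the list did not pass (camera adjusted p = 0.0977). Among markers of other cell types, 2 of 8 goblet and endocrine genes fell (AGR2 at −2.54 and LYZ at −2.38; camera adjusted p = 0.0227; adjusted p = 0.161 with an estimated correlation). LYZ and CD14 (−1.07) were the 2 of 6 immune genes that fell (camera adjusted p = 0.077), and TAGLN (−1.22) was the 1 of 9 fibroblast genes (camera adjusted p = 0.662), with the same counts for these 3 lists adjusted over the list alone. In all, 15 of the 20 lists passed, 5 higher and 10 lower, and 8 (3 higher, 5 lower) with an estimated correlation.

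**Figure D3:**
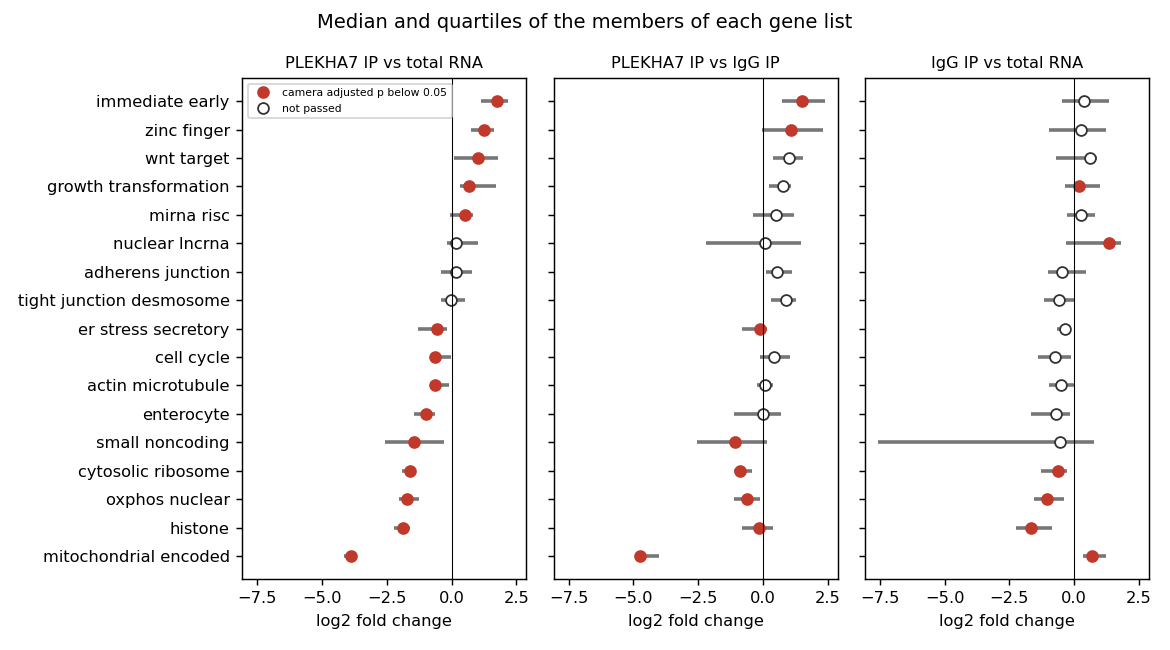
Median (point) and quartiles (bar) of the log2 fold changes of the members of 17 gene lists in the 3 comparisons, the immune, fibroblast and goblet lists being left out. Red marks lists with a camera adjusted p under 0.05 at the preset correlation; 1 of the 8 lists marked for PLEKHA7 against IgG, 8 of the 14 against total RNA and 0 of the 6 for IgG against total RNA also pass with an estimated correlation.

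The comparison of PLEKHA7 with IgG asks which transcripts exceed unspecific capture. The PLEKHA7 transcript stood at 1018 ± 172 CPM in its immunoprecipitates and at 153 ± 150 CPM in IgG (SD, n = 4), a log2 fold change of 2.75 (SE 0.62) that was positive in 4 of 4 experiments and did not pass (edgeR adjusted p = 0.0723). With the experiment as a block it passed, at 3.21 (SE 0.55, edgeR adjusted p = 5.23e-06). That p value carries the limit given above for blocked fits with IgG. Leaving out single libraries gave 2.22 to 3.78, the highest without IgG library 2, where PLEKHA7 also passed. Mitochondrial mRNAs fell, with MT-ND4 at −4.98, MT-CO3 at −4.86 (SE 0.46), MT-CYB at −4.85, MT-ND1 at −4.70 and MT-ND5 at −4.01. The non-coding RNAs RN7SK (−5.40, SE 0.53, edgeR adjusted p = 0.000736) and RPPH1 (−3.34, SE 0.38, edgeR adjusted p = 0.00221) fell as well.

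Of 15828 genes tested with edgeR, 22 changed, 0 higher and 22 lower, while at an unadjusted p under 0.05 there were 2159 higher and 656 lower. The smallest edgeR adjusted p among higher genes was 0.0662. DESeq2 called 2106 genes, 695 higher and 1411 lower, and the blocked edgeR fit 62, 20 higher and 42 lower. Besides those above, the largest falls were RN7SKP230 (−9.60), 7SK (−8.67), AATK-AS1 (−8.46), AL807752.1 (−6.56, blocked edgeR adjusted p = 0.0875), AC079949.1 (−6.40), AL161626.1 (−6.23) and the nuclear copies of mitochondrial genes MTND2P28 (−5.39) and MTATP6P1 (−5.20). Among the genes that did not pass, the log2 fold change was 2.26 for MYC (edgeR adjusted p = 0.0755), 3.85 for JUN (0.13), 0.81 for CTNND1 (0.299), 0.52 for CCND1 (0.624), 0.07 for CDH1 (0.953), 0.09 for ACTB (0.935), −0.28 for GAPDH (0.755) and −0.22 for SNAI1 (0.956), whose 16 IgG counts were all in 1 library. The sign of SNAI1 is not settled, since it was higher in 3 of 4 experiments, at 2.25 with the block and at −0.61 to 9.26 without single libraries. JUN, also with 16 IgG counts, was at 4.94 with the block and at 3.32 to 5.67 without single libraries. The median of all genes was 0.403. With the read totals behind the deposited RPKM values as library sizes it was 3.79, with 11418 genes higher and 15 lower and GAPDH at 2.99. Experiments 1 and 4 alone gave 1 gene and experiments 2 and 3 alone gave 0, with 4 libraries in each fit. Leaving out IgG library 1 or 2 gave 12 or 49 genes, with 18285 or 18569 genes tested.

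Of the gene lists, 9 passed against IgG, and only the mitochondrially encoded list also did so with an estimated correlation. In it 5 of 12 genes fell over all genes and 12 adjusted over the list alone (camera adjusted p = 7.53e-41; adjusted p = 0.00914 with an estimated correlation). The zinc finger list was higher (camera adjusted p = 1.34e-05; adjusted p = 0.24 with an estimated correlation). None of its 411 members passed over all genes, 37 were higher and 1 lower adjusted over the list alone, and 31 had no count in any IgG library. Immediate early genes were higher as a list (camera adjusted p = 0.0127; adjusted p = 0.253 with an estimated correlation) with a median of 1.51. FOSL2 was at 1.54 and GADD45B at 4.63, and none of 25 passed over all genes or adjusted over the list alone. Cytosolic ribosomal genes (camera adjusted p = 1.07e-17; adjusted p = 0.132 with an estimated correlation) were lower, with RPL37 at −1.86 and none of 81 passing over all genes and 3 lower adjusted over the list alone. Oxidative phosphorylation genes (camera adjusted p = 1.58e-06; adjusted p = 0.132 with an estimated correlation) and endoplasmic reticulum genes (camera adjusted p = 0.00291; adjusted p = 0.132 with an estimated correlation) were lower as lists with 0 members passing either way. The endoplasmic reticulum median was −0.12, so that list was lower mainly relative to all genes, whose median was 0.403. Small non-coding genes were lower as a list (camera adjusted p = 7.58e-11; adjusted p = 0.132 with an estimated correlation), RN7SK and RPPH1 being the 2 of 81 that passed over all genes, with 5 lower and 1 higher adjusted over the list alone. Histone genes (camera adjusted p = 0.0127; adjusted p = 0.351 with an estimated correlation) were lower with 0 of 55 passing either way. Their median of −0.16 and mean of −0.05 were likewise low mainly relative to all genes. Fibroblast markers (camera adjusted p = 0.0152; adjusted p = 0.211 with an estimated correlation) were lower with 0 of 6 passing over all genes and 2 lower adjusted over the list alone, COL6A3 at −6.48 and FN1 at −1.31. The other 11 lists did not pass. Their medians ran from 0.02 for enterocyte genes to 1.01 for Wnt targets, apart from the immune list, whose median of 4.35 over 4 genes became 0.71 with the 2 genes absent from IgG set at their bound. The nuclear long non-coding, enterocyte, actin and goblet lists had positive medians and means while the test, which compares a list with all other genes, pointed down. Adjusted over the list alone they gave 1 higher adherens junction gene, which was PLEKHA7 itself, 1 higher and 1 lower microRNA and RISC gene, 1 higher and 3 lower nuclear long non-coding RNAs, 1 higher enterocyte gene, 2 higher Wnt targets, 2 higher immune genes and 0 genes of the rest. With the block the nuclear long non-coding (camera adjusted p = 0.0247), enterocyte (0.044) and actin (0.00768) lists were lower as well. The deposited read totals as library sizes turned the endoplasmic reticulum list to higher (camera adjusted p = 0.601) and the actin list to higher (9.27e-05).

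The comparison of IgG with total RNA measures what the control captured. BRSK2, a kinase gene, was the 1 gene of 17246 that passed in edgeR, at a log2 fold change of 8.26 (SE 0.73, adjusted p = 0.00708), with 1121 ± 964 CPM in IgG and 3.66 ± 0.804 CPM in total RNA (SD, n = 4). The PLEKHA7 transcript was at 143 ± 144 CPM in IgG and 27.1 ± 6.66 CPM in total RNA, a log2 fold change of 2.39 (SE 0.76) that was positive in 4 of 4 experiments and did not pass (edgeR adjusted p = 0.102, blocked 0.335). Leaving out single libraries gave 1.34 to 2.77 for PLEKHA7, the lowest without IgG library 2. CDH1 was at −1.15 (edgeR adjusted p = 0.0686), GAPDH at −1.20 (0.0877; −1.33 and 0.0376 with the block), ACTB at −0.91 (0.155), CTNND1 at −0.46, MYC at −0.35, JUN at −0.41, CCND1 at 0.52 and SNAI1 at 1.54. SNAI1 was lower in 3 of 4 experiments and at −1.17 with the block. Leaving out single libraries gave −8.55 to 2.09 for SNAI1 and −2.45 to 0.14 for JUN, so these signs are not settled.

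At an unadjusted p under 0.05 there were 951 higher and 2975 lower genes in IgG. DESeq2 called 3573 genes (2521 higher, 1052 lower) and the blocked edgeR fit 102 (19 higher, 83 lower). The genes with the next smallest p, none of which passed, were SLC6A11 (11.20), AL161626.1 (9.39), AL807752.1 (9.17), LRRC10B (5.88), HOXD3 (6.65), OTUD5 (3.99), PRRG3 (7.07), SLC35D3 (10.08) and DUX4L8 (11.04). With the block SLC6A11 (edgeR adjusted p = 2.4e-06), AL161626.1 (1.3e-31), AL807752.1 (0.0044), OTUD5 (0.000507), SLC35D3 (0.0366) and DUX4L8 (0.0178) passed. The limit given above for blocked fits with IgG holds for these calls too. The count was 2070 without IgG library 1, 1397 without IgG library 2 and 0 without any 1 of the total RNA libraries, where BRSK2 had edgeR adjusted p values of 0.0504 to 0.0585. The low-count filter also moved: 19963 and 20141 genes were tested without IgG library 1 and 2, and 11206 to 11270 without a total RNA library. Without IgG library 3 or 4, with 20039 and 20097 genes tested, the count was 1. How far the filter moved the counts was not tested. The count was 0 in either pair of experiments alone. With the deposited read totals the median of all genes was −3.55 and 23 genes were higher and 11667 lower, CCND1 turning to −2.64.

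None of the members of any list passed over all genes in IgG against total RNA. As lists, growth and transformation genes (camera adjusted p = 0.00823; adjusted p = 0.386 with an estimated correlation), mitochondrially encoded mRNAs (camera adjusted p = 0.00153; adjusted p = 0.386 with an estimated correlation) and nuclear long non-coding RNAs (camera adjusted p = 0.00823; adjusted p = 0.386 with an estimated correlation) were higher. Examples are KCNQ1OT1 at 2.96, MALAT1 at 1.77 and MT-CYB at 1.23. Histone genes (camera adjusted p = 2.38e-07; adjusted p = 0.105 with an estimated correlation), with HIST1H4C at −1.97, were lower, as were oxidative phosphorylation genes (camera adjusted p = 0.00153; adjusted p = 0.386 with an estimated correlation), with NDUFC2 at −1.70. Cytosolic ribosomal genes were lower (camera adjusted p = 0.0469; adjusted p = 0.588 with an estimated correlation), but not with the block (camera adjusted p = 0.205). The block added the microRNA and RISC (0.0165), zinc finger (0.0326) and Wnt target (0.0368) lists as higher. Adjusted over the list alone, 21 histone genes were lower, 27 zinc finger genes lower and 2 higher, and 22 small non-coding genes lower and 3 higher. The same adjustment gave 5 enterocyte genes lower, 2 nuclear long non-coding RNAs higher and 1 lower, 2 immune genes lower, 1 actin list gene lower, and 0 genes of the other lists. Medians of the lists that did not pass ran from −1.78 for goblet and endocrine genes to 0.60 for Wnt targets, apart from the immune list, in which CD14 and CSF1R had no IgG counts. For the adherens junction and small non-coding lists the median and mean were negative and the test, which compares a list with all other genes, pointed up, and for zinc finger genes the mean alone was negative.

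Genes enriched over both controls at once are what the design looks for. No gene of the 15803 tested in both edgeR comparisons was higher against both, with 0 higher against IgG and 3990 against total RNA. At an unadjusted p under 0.05 the comparison with IgG had 2159 higher genes, and DESeq2 gave 326 genes higher against both. With the experiment as a block 15 genes were higher against both, under the limit given above for blocked fits with IgG. Lists of the same sizes, taken by smallest p from 10 simulations of unchanged libraries, shared 8.3 genes on average and at most 13, because both comparisons use the same PLEKHA7 libraries. The 15 were PLEKHA7 (log2 fold change 3.21 against IgG and 4.99 against total RNA), RNF43 (2.54 and 2.96), the Wnt corepressor TLE3 (2.24 and 2.69), GPBP1 (2.32 and 2.20), ZMYND8 (2.58 and 1.73), SLMAP (2.46 and 1.24), WDR20 (3.46 and 1.38), the RNA-binding protein gene RBM47 (3.02 and 0.66), C11orf82 (4.94 and 1.32), DLGAP4 (5.34 and 1.82), ZNF131 (5.02 and 1.34), SETDB1 (6.72 and 0.54), ZNF415 (7.47 and 1.56), ZNF821 and RASGEF1B. SETDB1 and ZNF415 had counts in only 1 IgG library, C11orf82, DLGAP4 and ZNF131 in 2, and ZNF821 and RASGEF1B in 0, so their log2 fold changes against IgG rest on few counts. Without the block SETDB1 was at −0.56 against IgG, ZNF415 at 3.33 and C11orf82 at 2.20. The 10 genes nearest to passing without the block included ZNF821, RASGEF1B, ZNF17, EXO5, ZNF155, ZNF461, USP2 and HEXIM2, which had 0 counts in all IgG libraries. Against the limit of 3 counts over the IgG group they were at least 94.8-fold, 89.6-fold, 63.3-fold, 57.4-fold, 48.4-fold, 50.5-fold, 43.2-fold and 37.9-fold higher. This limit covers counting error only, and none of these genes passed against IgG without the block. Of the 15828 genes tested against IgG, 1091 had 0 counts in all IgG libraries, so that absence does not set these genes apart. Over total RNA, ZNF821 rose by 2.12, RASGEF1B by 1.61, ZNF17 by 1.72, EXO5 by 1.83, ZNF155 by 1.8, ZNF461 by 1.99, USP2 by 2.08 and HEXIM2 by 1.13. The others were the nuclear receptor NR2F2 (1.83 against IgG, edgeR adjusted p = 0.0723, and 1.95 against total RNA) and ELF1 (2.36, 0.0723, and 1.70). Of the genes higher against total RNA, 81.4% had a positive log2 fold change against IgG, compared with 61.4% of all genes; in the simulations lists of that size had 60 to 64.5% and all genes 51.6 to 56.2%. Lower against both were 16 genes. Simulated lists of the same sizes shared 14.5 on average and at most 16, so the overlap says little beyond the sizes of the lists. At the threshold itself the simulations called 0 genes lower against both, so they do not show that shared libraries alone give such calls. With the block 25 genes were lower against both and the simulated lists shared 26.4 on average. The 16 include 7SK, RN7SK, RPPH1 and the 5 mitochondrial mRNAs above.

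Across 20916 genes, which are not independent replicates, the PLEKHA7 and IgG log2 ratios over total RNA correlated with Pearson's r 0.234 and Spearman's rho 0.227. Simulated unchanged libraries that share the total RNA gave r 0.05, and separate total RNA libraries for each ratio gave r 0.209. The covariance was 0.547, of which 0.498 remained after subtracting the simulated value of 0.049. In single experiments r was 0.083 to 0.247.

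Mitochondrially encoded mRNAs held 0.0193 ± 0.00237% of counts in PLEKHA7 libraries, 0.271 ± 0.0469% in total RNA and 0.461 ± 0.277% in IgG (SD, n = 4). PLEKHA7 libraries differed from both (exact permutation p = 0.0286, the smallest possible, adjusted over 15 comparisons 0.0476), and the difference between IgG and total RNA did not pass (exact p = 0.0857, adjusted 0.117), although it did with all exon lines summed (0.12 percentage points, exact p = 0.0286). Cytosolic ribosomal protein mRNAs held 3.28 ± 0.502% in PLEKHA7, 7.51 ± 0.716% in total RNA and 5.62 ± 2.19% in IgG, and PLEKHA7 differed from total RNA (adjusted exact p = 0.0476) but not from IgG (adjusted exact p = 0.117). Histone mRNAs held 0.228 ± 0.0405% in PLEKHA7 and 0.254 ± 0.0579% in IgG, both lower than the 0.653 ± 0.0577% of total RNA (adjusted exact p = 0.0476). Small non-coding RNAs held 0.328 ± 0.097% in PLEKHA7, 2.16 ± 1.04% in total RNA and 1.63 ± 0.786% in IgG, with PLEKHA7 lower than both (adjusted exact p = 0.0476). The 10 most abundant genes held 3.20 ± 0.717% in PLEKHA7, 6.36 ± 1.82% in total RNA and 14 ± 11.9% in IgG, with PLEKHA7 lower than both (adjusted exact p = 0.0476). IgG library 1 held 31.3% and the others 5.81 to 12%, and without it the difference between PLEKHA7 and IgG went from −10.8 to −4.97 percentage points.

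Over 10972 genes the median log2 ratio of counts in the last to the first exon was 3.58 ± 0.157 in PLEKHA7 and 3.58 ± 0.015 in total RNA (SD, n = 4; exact two-sided permutation p = 0.971). Over 607 genes with enough IgG counts it was 4.58 ± 0.026 in PLEKHA7 and 5.50 ± 0.472 in IgG, a difference of −0.922 (exact p = 0.029, adjusted 0.0435). Over 608 genes IgG exceeded the total RNA value of 4.87 ± 0.051 by 0.631 (exact p = 0.029, adjusted 0.0435). With the ratio of summed counts in place of the median over genes, the difference between PLEKHA7 and IgG turned to 0.511 (exact p = 0.0286) and that between IgG and total RNA to −0.0525 (exact p = 0.6). The difference between PLEKHA7 and total RNA became 0.233 (exact p = 0.0286).

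PLEKHA7 lies on chromosome 11 of hg19, on the minus strand, from 16799842 to 17035990, and the table held 63 distinct intervals for it. The rise over total RNA covered the transcript, with the 55 intervals that had at least 20 total RNA counts at log2 ratios of 4.56 to 6 and a median of 5.04. The last exon, from 16799842 to 16800567, has 726 bases of which 20 are coding, and its log2 ratio was 4.60 ± 0.54 (SD, n = 4), against 5.03 ± 0.63 for all intervals together. In IgG libraries 17 to 41 of the intervals held counts. Elsewhere on hg19, JUN is on chromosome 1 from 59246465 to 59249785, MYC on chromosome 8 from 128747680 to 128753674, CDH1 on chromosome 16 from 68771128 to 68869451 and RNF43 on chromosome 17 from 56429861 to 56494956.

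**Figure D4:**
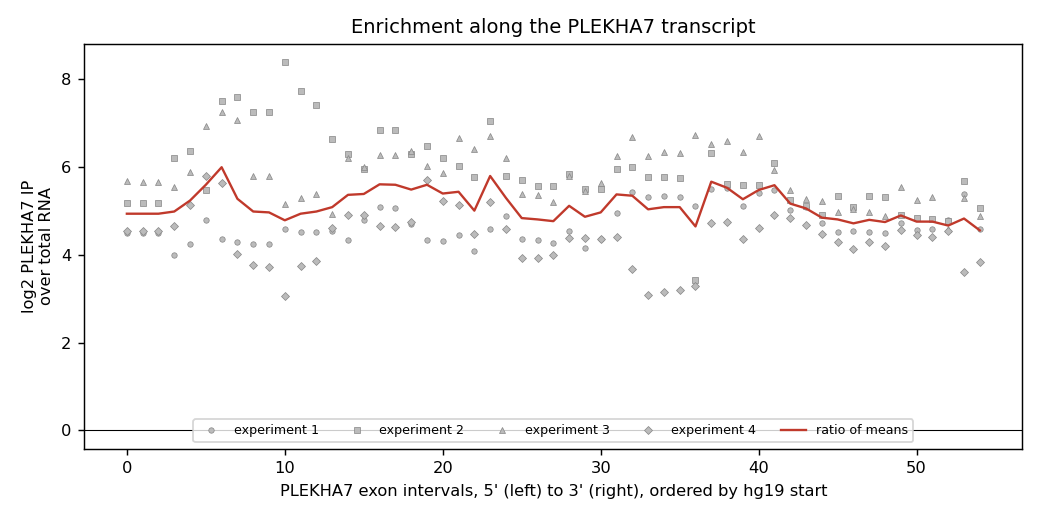
Log2 ratio of PLEKHA7 immunoprecipitate to total RNA in CPM for 55 exon intervals of the PLEKHA7 gene, in order from the 5′ to the 3′ end, with 1 point per experiment and a line for the ratio of means. The line stays between 4.56 and 6, and ends at the right with the last exon at 4.56.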

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

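Chosen only after the result was seen were the tests on the last PLEKHA7 exon, on carry-over between libraries, on the scaling of the IgG libraries and on total RNA background, the test of shared capture on the mitochondrially encoded list, and the restriction to pairs of experiments; the tests on splits of the libraries, on length and GC content, on abundant RNAs and on shared capture were written down before. The bounds for total RNA background were first set on the median and moved to both quartiles after the values were seen; on the median alone the background would fit the mitochondrial mRNAs and not the rest as 1 set. The genes lower than IgG were first split in 2 parts for that test, and the small non-coding list was parted from the rest after their values were seen, with fewer than 5 genes then set to decide nothing. A stricter bound for scaling, on the calls that remain, was tried after the first and dropped, because losing calls to a shift of all genes does not bear on these genes.

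The zinc finger and growth and transformation lists were higher in PLEKHA7 immunoprecipitates than in total RNA. The oxidative phosphorylation, mitochondrially encoded and histone lists were lower, and 8431 genes changed in all. Only 1 of 35 splits of the 8 libraries, the real one, gave as many, the highest other split giving 0. Every other split puts libraries of both groups on each side, which widens the spread within a side and leaves few calls. The splits can thus show at most that the groups differ, not why, here and in the comparisons below. Removing mitochondrial and small non-coding genes before normalization left 99.5% of the calls on the remaining genes. The median of all genes went only from 0.002 to 0.007, so these RNAs hardly moved the scaling, and other abundant RNAs were not tested. Removing a smooth trend on exonic length and GC content left 80% of the calls with a GC value in their direction (80.2% with the block; 84.3% of calls had a value), which argues against that trend as the whole cause. The trend moved the medians of small non-coding genes from −1.42 to −0.28, histone genes from −1.87 to −1.10, microRNA and RISC genes from 0.52 to 0.11 and adherens junction genes from 0.18 to −0.28, so it can account for part of these. Capture shared with IgG is argued against for the mitochondrially encoded list, which lay at least 1.24 above all genes in IgG over total RNA in every experiment (log CPM; by edgeR the list was at 0.68 and all genes at −0.35, a smaller gap) and at −3.90 in PLEKHA7. The histone list was low in IgG too, with a median of −1.68 over total RNA, against −1.87 in PLEKHA7. Its median for PLEKHA7 against IgG was −0.16, so a fall particular to PLEKHA7 was not shown for it. For the other genes shared capture cannot be told apart from a biological explanation, that these mRNAs associate with PLEKHA7 complexes. The slope of IgG over total on PLEKHA7 over total across 2778 abundant genes was 0.26, 0.25 and 0.46 in experiments 1, 3 and 4 but 0.92 in experiment 2. Experiments 1 and 4 alone gave 722 genes and experiments 2 and 3 alone 7563, with 4 libraries in each fit, and all 12 libraries in 1 fit gave 230.

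The PLEKHA7 transcript was the named gene with the largest rise over total RNA in its own immunoprecipitates and was also above total RNA in IgG libraries. DNA or cDNA of the coding sequence is argued against by the last exon, nearly all of it untranslated, whose log2 ratio was at least 3.85 in every experiment; DNA or RNA of the whole gene was not tested. Carry-over of PLEKHA7 library material into IgG libraries was tested on 50 other enriched genes: the PLEKHA7 transcript would need shares of 2.7%, 36.6%, 1.4% and 10.5% in experiments 1 to 4, and the median shares of the 50 genes were 8.2%, 31.4%, 0% and 3%, with quartiles that include all 4 needed shares, so it cannot be told apart. An earlier form of that test, on summed counts, gave 113%, 209.3%, 137% and 612.5%, all above what carry-over needs; it was replaced after being seen, since genes that exceed their level in the PLEKHA7 libraries dominated the sums, above all AL161626.1 (27190 of 33020 CPM in experiment 4), and no carry-over can pass 100%. No biological explanation, such as capture of the mRNA through its nascent protein, was tested.

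Against IgG 22 genes were lower in PLEKHA7 immunoprecipitates, where the highest other of 35 splits gave 1 gene and 1 split, the real one, gave as many. With the deposited read totals as library sizes the median log2 fold change of the 22 went from −4.86 (quartiles −6.02 to −4.65) to −1.62 (quartiles −2.43 to −1.26). Of the 22, 21 stayed below 0, although only 8 of the calls remained (6 with the block) as all folds shifted up. This choice of library sizes alone thus did not bring the genes to their level in IgG. It cannot exclude scaling of the shallow IgG libraries, because the 22 were picked as low from the same data. Their gap to the median of all genes, −5.26 before and −5.41 after, decides nothing, because library sizes shift all folds nearly alike. A background of total RNA in IgG libraries that PLEKHA7 libraries lack cannot be told apart for 12 mitochondrial mRNAs and their nuclear copies, whose IgG level over total RNA was 0.93 above the median of all genes, with quartiles of 0.79 to 1.34 across the bound of 1 set for it, nor for RN7SK and RPPH1, at 0.44, which are too few. The 8 others as a set lay 7.78 above, with quartiles of 3.03 to 9.43. Of them 6, BRSK2 and AL161626.1 included, lay more than 2 above, while 7SK and RP11-750B16.1 lay within 1. Both quartiles of this set are beyond what such a background allows. They cannot exclude it, because the 22 were picked as higher in these same IgG libraries, which builds in part of the height. All parts were first tested together, at 1.1, and split after that was seen. No biological explanation was tested.

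The single gene called between IgG and total RNA, BRSK2, came from the 1 of 35 splits that gave any gene, the highest other split giving 0. Simulated 8-fold changes were recovered at 0% in this comparison, so counts of 0 in the other splits say little. In splits that part all 4 same-numbered pairs the highest other count was 0 in all 3 comparisons.

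Of 148 groups of 4 libraries tested, 20 had 1 library far from the other 3, where chance flags about 1 in 20 groups, or 7.4. That figure holds for independent groups with normally distributed values. Most groups here were CPM of genes picked for large folds, some near 0, and several flags fell on the same library. An excess over chance is therefore not shown. In IgG experiment 4, gene counts per read were 0.0607, against 0.176 to 0.193 in the other IgG libraries. In the same library, in normalized CPM, BRSK2 stood at 2556 (others 515 to 801), AL161626.1 at 27190 (4396 to 7575), AL807752.1 at 183 (32.6 to 51.3), SLC6A11 at 286 (34.7 to 73.7) and DUX4L8 at 131 (4.57 to 20.3). In IgG experiment 3 the mitochondrially encoded share was 0.875%, against 0.303 to 0.356%, and SNAI1 was at 9.47 CPM with 0 in the others. In PLEKHA7 libraries 7SK was at 13.2 CPM in experiment 2 (others 0.694 to 1.54), EXO5 at 44.6 in experiment 2 (33.6 to 35.4), NR2F2 at 716 in experiment 3 (617 to 623), RASGEF1B at 30.8 in experiment 4 (63.6 to 69.3), RPL39P3 at 0.263 in experiment 4 (0.0925 to 0.0957) and AATK-AS1 at 0.685 in experiment 4 (0.216 to 0.293). RN7SL1 was at 125 CPM (others 26.7 to 41.2) and AC084082.3 at 0.432 CPM (others 0) in PLEKHA7 experiment 1. In total RNA RASGEF1B was at 23.9 CPM in experiment 4 (16.8 to 17.8), ZBTB7A at 1.92 in experiment 1 (0.867 to 0.939), LRRC10B at 0.187 in experiment 2 (0.0212 to 0.0358) and SLC6A11 at 0.0079 in experiment 1 (0.0531 to 0.0622).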

How the results depend on the processing

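Chosen after seeing the data were the deposited read totals as library sizes, the pairs of experiments alone and the length and GC trend; the other alternatives were fixed before. Simulated 8-fold changes against IgG were mostly missed, and the depth of the IgG libraries and their spread (biological coefficient of variation 0.931 against IgG and 0.4 against total RNA) were not separated. For PLEKHA7 against IgG, against total RNA, IgG against total RNA and genes higher against both controls, counts of 22, 8431, 1 and 0 became 2106, 3573 and 326 with DESeq2 (for all but PLEKHA7 against total RNA, as in the next 3), 761, 740 and 39 without a low-count filter, 775, 878 and 239 with at least 50 counts in at least 4 libraries, and 62, 102 and 15 with the experiment block, which also gave 25 in place of 16 genes lower against both. All 12 libraries in 1 fit gave 2463, 230, 2015 and 33, the deposited read totals 11433, 5422, 11690 and 3156, and these with the block 12598, 3787, 11272 and 2397. Non-overlapping exon intervals gave 61, 26 and 7 for all but PLEKHA7 against total RNA, and all exon lines summed gave 13 against IgG and 880 for IgG against total RNA. IgG against total RNA gave 3 with DESeq2 size factors and 3 with library totals. PLEKHA7 against IgG gave 10 without mitochondrial and small non-coding genes, and against total RNA 5346 with an added 2-fold threshold. Experiments 1 and 4 alone gave 1, 722 and 0 in the 3 comparisons, and experiments 2 and 3 alone gave 0 for PLEKHA7 against IgG and 0 for IgG against total RNA. Leaving out each library gave 12 to 49 (IgG library 1 and 2), 6684 to 9024, 0 to 2070 (each total RNA library, and IgG library 1; 1397 without IgG library 2) and 0 to 19 (IgG library 2; 1 without IgG library 4). With an estimated correlation 1, 8 and 0 lists passed in place of 9, 15 and 6, and leaving out each library gave 3 to 9 lists for IgG against total RNA. The share of mitochondrially encoded mRNAs in IgG exceeded that in total RNA by 0.12 and past the threshold with all exon lines. With the deposited read totals GAPDH turned to 2.99 against IgG, CCND1 to −2.64 in IgG against total RNA, and the endoplasmic reticulum (camera adjusted p = 0.601) and actin (9.27e-05) lists turned higher against IgG. The exon position differences turned to 0.233 for PLEKHA7 against total RNA, 0.511 against IgG and −0.0525 for IgG against total RNA with summed counts. The cause was not tested for any of these, beyond the changed number of libraries or genes in the fits that leave some out. Of the remaining results, the alternatives kept 1080 values of single named genes on their side of the threshold, moved 129 past it and 39 short of it, and for gene lists 614, 46 and 46; the correlation across genes stayed between 0.166 and 0.258 without single libraries.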

Other observations

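The gene families below, the alternatives named with them and the test of the hypothesis were chosen only after these data were seen, so their counts are not independent of the choice. Among transcription factors of the KLF, SOX and FOX families 36 of 48 rose in PLEKHA7 immunoprecipitates over total RNA and none fell, including FOXK2 (2.04), SOX4 (1.70), KLF5 (1.60) and KLF12 (1.58), with a median of 1.37 (camera adjusted p = 5.7e-14; adjusted p = 0.0299 with an estimated correlation). Histone-modifying enzymes had 24 of 42 genes higher and 3 lower, with SETD5 at 1.92 and KMT2E at 1.69 (camera adjusted p = 1.08e-06; adjusted p = 0.0299 with an estimated correlation). Kinases of the MAPK cascades had 12 of 20 higher and 1 lower, with MAP3K8 at 1.75 and MAP3K13 at 1.09 (camera adjusted p = 0.000189; adjusted p = 0.0294 with an estimated correlation). RING finger genes had 27 of 65 higher and 9 lower, with RNF111 at 1.34 and RNF7 at −1.09 (camera adjusted p = 0.0029; adjusted p = 0.0452 with an estimated correlation). When a trend on length and GC content was removed, the medians of these 4 families, in the order named, went from 1.37, 0.54, 0.79 and 0.46 to 1.11, 0.22, 0.49 and 0.31.

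Proteasome genes fell, 33 of 36 with none higher, with PSMC6 at −1.73 and PSMA4 at −1.59 (camera adjusted p = 1.07e-20; adjusted p = 0.0299 with an estimated correlation). Genes of the mitochondrial ribosome fell, 64 of 76 with none higher, with MRPL13 at −2.04 and MRPL47 at −1.63 (camera adjusted p = 3.7e-17; adjusted p = 0.0452 with an estimated correlation). Tetraspanins and cathepsins, proteins of membranes and lysosomes, had 19 of 34 lower and 2 higher, with CTSC at −2.07 and CD151 at −1.96 (camera adjusted p = 8.19e-10; adjusted p = 0.0236 with an estimated correlation). TMEM genes had 63 of 191 lower and 17 higher, with TMEM59 at −2.56 (camera adjusted p = 0.0045; adjusted p = 0.0328 with an estimated correlation), and solute carriers had 69 of 238 lower and 27 higher without passing as a list (camera adjusted p = 0.0922).

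One hypothesis was that mRNAs translated at the endoplasmic reticulum may be lower in the immunoprecipitates than mRNAs translated in the cytosol. It would need the 463 solute carrier, TMEM, tetraspanin and cathepsin genes to lie at least 0.5 below the 112 proteasome and mitochondrial ribosome genes. They lay 0.8 above, with medians of −0.28 (quartiles −0.88 to 0.25) and −1.08 (quartiles −1.38 to −0.75), and 0.64 to 0.75 above in single experiments. That passed the bound first set against the hypothesis, which was changed after it was seen; the test decides nothing, because the reference families were chosen after their fall was seen and the solute carriers include mitochondrial ones.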
